A study of Drosophila melanogaster and Drosophila simulans and Drosophila yakuba with 8 samples.

How the data were processed

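Per the labels, messenger RNA of dissected testes from adult flies was sequenced as single-end Illumina libraries, with 2 libraries each of Zeus knockdown, Caf40 knockdown and wildtype D. melanogaster and 1 each of wildtype D. simulans and D. yakuba. The knockdowns used the germline driver nos-Gal4 with an RNA interference construct, per the labels. All 6 D. melanogaster libraries carry the same strain label, and a library with the driver alone was not analysed here.

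Per the submitters' processing notes, reads were aligned with Bowtie, and the D. melanogaster reads to the dm3 genome build. The aligner version, the annotation release and the handling of reads that match several places are not given in the sources used here. Per the file headers, the authors deposited raw read counts per gene, split into reads on the genome and reads on exon junctions, together with the exon length of each gene, the library totals and an RPKM value. Each deposited count was a whole number and the sum of its genome and junction parts. The deposited RPKM equalled the gene's reads divided by its listed length in kilobases and by the library's mapped reads, in the usual RPKM scale, for every listed gene. No library was pooled.

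The 15178 D. melanogaster identifiers were named from a current gene table of the BDGP6 assembly, which gave a symbol to 12862 of them (84.7%). Because that assembly is not the authors' build, it served only for names, chromosome arms and the order of neighbouring genes, and coordinates are not given. Identifiers of D. simulans and D. yakuba had no symbols in the table and shared 0 entries with each other or with D. melanogaster. The planned comparison across species, and that of the knockdown response with the species difference, were therefore not run. Lengths listed for D. simulans and D. yakuba were multiples of 3 for 97.4% and 97.0% of genes and are coding lengths.

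The groups, the comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The plan named limma on log2(RPKM + 1) unless raw counts were present, and edgeR on counts if they were. As the files hold counts, edgeR 4.0.16 in R 4.3.3 was used, with TMM scaling and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean RPKM of at least 1 over the 6 D. melanogaster libraries were tested (10223 genes, 8970 with a symbol). The 3 groups shared 1 estimate of the spread (common biological coefficient of variation 0.0747), because each had 2 libraries, and no block was used. The contrasts were each knockdown minus wildtype and Zeus minus Caf40 knockdown. Printed RPKM values are the authors', scaled by mapped reads, while log2 fold changes carry TMM factors between 0.881 and 1.19, so a ratio of mean RPKM values differs somewhat from the fitted fold change. Standard errors are the log2 fold change over the square root of the F statistic. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so p-values rest on the model that shares information among genes.

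Replicates were checked before averaging. A chi-square statistic per degree of freedom of 2.11 for the Zeus knockdown, 15.4 for the Caf40 knockdown and 5.48 for wildtype showed that no pair was 1 library deposited more than once. The correlation of log2 RPKM across genes was 0.996, 0.992 and 0.996 for these pairs. Scaling matters in these data, because other scalings moved the median log2 fold change. Scaling by library total shifted it by -0.16 for Zeus, 0.22 for Caf40 and -0.38 for the difference, scaling to the same median RPKM by 0.10, -0.30 and 0.40, and DESeq2 size factors by 0.02, -0.06 and 0.08. The groups also differed in the share of reads taken by abundant genes.

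Genes are named by rule. Rcd-1r and Rcd-1 are always given. For each knockdown, the 12 largest rises and the 12 largest falls are named among genes past the threshold with a group mean of at least 5 RPKM in either group and no overlap between replicates, and for the difference between knockdowns the 8 largest each way. Up to 4 members with the smallest p are taken from each list. With a group at 0 reads, the fold is a lower bound against a floor of 3 reads over the group. With 1 to 3 reads, a ratio with an exact 95% binomial counting interval is given. PCR reads are not independent molecules, so such intervals cover counting error only. Sdic copies and other near-identical genes, overlapping genes and antisense genes can share reads, and their values are uncertain.

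The 22 lists tested covered CCR4-NOT, messenger RNA decay and P bodies, meiotic arrest, spermatocyte meiosis, postmeiotic spermatids, comet and cup genes, stem cells and spermatogonia, the piRNA pathway, cyst and hub cells, accessory gland and duct, muscle sheath, fat body and yolk, gut and Malpighian tubules, antimicrobial peptides, heat shock, testis-specific and general proteasome, testis-specific mitochondrial copies, Y-linked fertility genes, dynein and axoneme, replication and cell cycle, and cytoplasmic ribosomal proteins. A further list held the 2 targets and had no set test. Camera (limma 3.58.1) was run with a preset correlation of 0.01 on the edgeR object, where the plan had a limma fit. An estimated correlation and fry were also used. In the meiosis list the planned symbol SNM was matched as SA2, and in the mitochondrial list ND-AGGGL was matched as CG40472. Chromosome arms were compared by two-sided Fisher's exact tests, with 8954 tested genes on the arms.

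For the overlap of calls, 100 draws of unchanged groups were simulated. In each draw all libraries, wildtype included, were redrawn from the wildtype mean and the fitted dispersion. Both comparisons shared the redrawn wildtype libraries. The test was also checked on simulated counts with 200 changed genes. In the simulated Zeus comparison of 10223 genes, 92 of 100 genes changed 2-fold were recovered and 58 of 100 changed by log2 0.5, with 9 false among 159 calls. In the simulated Caf40 comparison 90 and 57 were recovered, with 7 false among 154 calls. A ribosomal list raised by log2 0.5 was called in the simulated Zeus and Caf40 comparisons with the preset correlation (adjusted p = 2.34e-166 and 2.2e-174, 0 other lists called) and with the estimated correlation (adjusted p = 0.00397 and 0.000949). The simulated genes were drawn independently of each other. In the data the estimated correlation of that list was 0.755 for Zeus and 0.739 for Caf40. The simulation therefore does not show that the test with an estimated correlation could find such a shift in these data.

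Alternatives tried were limma on log2(RPKM + 1) and with pseudocounts of 0.1 and 5, no filter, a filter of 5 RPKM, scaling to the same median, quantile normalization, only the 4 libraries compared, robust empirical Bayes, a 2-fold minimum, the replicate number as a block, DESeq2 1.42.0, and leaving out each library. Scaling by library total, DESeq2 size factors in edgeR, list tests with each library left out, list medians with limma and further gene families were added after the data had been seen. Where a library is left out, the lone sample of its group is assumed to vary like the other groups.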

Results

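Messenger RNA from dissected testes of adult flies was sequenced in 8 libraries from 3 Drosophila species. In Drosophila melanogaster the germline driver nos-Gal4 expressed an RNA interference construct against Zeus (2 libraries) or against Caf40 (2 libraries), and 2 further libraries came from wildtype testes. Drosophila simulans and Drosophila yakuba gave 1 wildtype library each. Caf40 is the gene Rcd-1 of the current annotation, a subunit of the CCR4-NOT complex that shortens the poly(A) tails of messenger RNAs. Zeus is Rcd-1r, a retrotransposed copy of Caf40 that is expressed in testis. The reference annotation places Rcd-1 on the X chromosome and Rcd-1r on arm 2L. The comparisons asked which testis transcripts depended on each copy and whether the responses to the loss of each copy differed.

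Reads assigned to genes numbered 12662615 and 22100567 in the Zeus knockdown libraries, 12837755 and 18070275 in the Caf40 knockdown libraries, and 24429722 and 22582003 in the wildtype libraries. The D. simulans library held 12863844 such reads and the D. yakuba library 59307734. At these depths, 3 reads on a gene of 1 kb corresponded to between 0.120 and 0.232 RPKM, reads scaled by gene length and by the mapped reads of the library, in the 6 D. melanogaster libraries. Between 9868 and 10220 genes had an RPKM of at least 1 in each D. melanogaster library. The most abundant transcript took between 1.08% and 1.49% of the gene reads in each of these libraries. The 100 most abundant genes took 24.3% and 24.2% of the gene reads in the Zeus knockdown, 19.4% and 20.6% in the Caf40 knockdown and 22.4% and 22.3% in wildtype. The median RPKM over all listed genes was 3.71 and 3.74 in the Zeus knockdown, 7.66 and 6.95 in the Caf40 knockdown, and 4.47 and 4.66 in wildtype. The labels do not say whether replicates came from separate flies, so p-values measure only the spread between these samples, which may be technical. No library with the driver alone was analysed here, and the labels give the same strain for all 6 libraries.

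Each construct lowered its own target, and the copy that was not targeted moved differently in the 2 knockdowns. Rcd-1r (FBgn0032089) measured 4.05 and 4.04 RPKM in the Zeus knockdown against 22.2 and 26.4 RPKM in wildtype, a fall of 5.42-fold (log2 fold change -2.44, SE 0.13, adjusted p = 1.07e-08, n = 2 per group). Rcd-1 (FBgn0031047) fell from 96.7 ± 2.21 RPKM in wildtype to 24.5 ± 1.71 RPKM (SD, n = 2) in the Caf40 knockdown (log2 fold change -2.21, SE 0.09, adjusted p = 1.21e-10). Rcd-1r rose to 124.2 ± 14.7 RPKM (SD, n = 2) when Rcd-1 was knocked down (log2 fold change 2.12, SE 0.10, adjusted p = 2.56e-10). Rcd-1 measured 78.6 ± 0.98 RPKM (SD, n = 2) in the Zeus knockdown and did not pass the threshold (log2 fold change -0.15, SE 0.09, adjusted p = 0.197). It did pass under several alternatives, for example with scaling by library total (log2 fold change -0.31, adjusted p = 0.00908), and also without Caf40 knockdown replicate 1 or 2 (-0.14 each, adjusted p = 0.0302 and 0.0267). Both genes differed between the knockdowns, Rcd-1 with a log2 difference of 2.06 (adjusted p = 1.76e-10) and Rcd-1r with one of -4.56 (adjusted p = 8.14e-12), Zeus minus Caf40. No exon-junction reads were counted on Rcd-1r in any library. The copies are related in sequence and how reads matching both were assigned is not given in the sources used here, so a small exchange of reads between them remains possible.

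**Figure D1:**
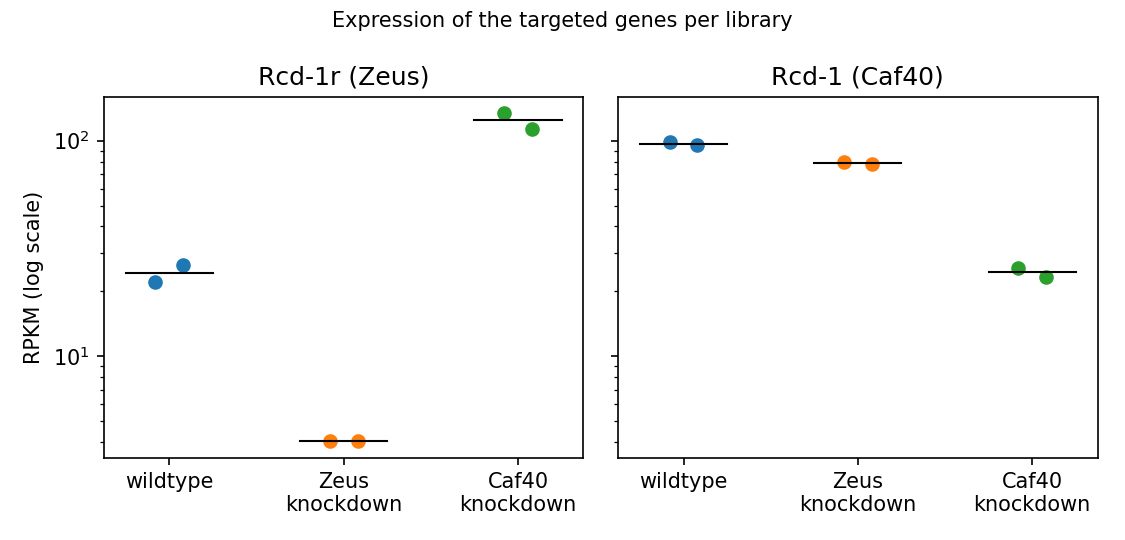
RPKM on a log axis of Rcd-1r (Zeus, left) and Rcd-1 (Caf40, right) in the 2 libraries each of wildtype, Zeus knockdown and Caf40 knockdown. Points are libraries and horizontal bars are group means, with Rcd-1r at a mean of 4.04 in the Zeus knockdown and 124.2 in the Caf40 knockdown.

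In the Zeus knockdown many testis transcripts changed by small amounts and a small set by large amounts. Of 10223 genes tested, 1715 rose and 2046 fell, which was 36.8% of the genes, and the median size of the log2 fold change over all tested genes was 0.26. At least 2-fold changes were found for 287 genes that rose and 313 that fell. Among the largest rises were DIP-delta, an immunoglobulin-domain cell-surface protein, from 0.638 ± 0.0325 to 22.2 ± 0.119 RPKM (SD, n = 2), and white (w), an ABC transporter of eye-pigment precursors, from 4.73 ± 0.254 to 83.6 ± 6.36 RPKM. The white transcript measured 70.8 and 79.6 RPKM in the Caf40 knockdown libraries, and without a driver-only library its rise could not be separated from a difference in genetic background between knockdown and wildtype flies. Among the largest falls were RabX2, a Rab-family GTPase, from 19.7 ± 1.03 RPKM to no reads, and CG31021, from 16.8 ± 1.21 to 0.120 ± 0.0460 RPKM.

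The 12 largest rises further included Henna (Hn), the phenylalanine hydroxylase, at 9.78 ± 4.0 RPKM against 0.0682 ± 0.0288 in wildtype (log2 fold change 7.19, SE 0.43, adjusted p = 2.31e-08). CG13675 rose from 0.272 to 27.4 RPKM, CG17177 from 0.627 to 36.9 RPKM and CG31199 from 0.341 to 8.46 RPKM, with log2 fold changes of 6.74, 6.02 and 4.72. CG17477 had no reads in wildtype and 5.60 ± 0.985 RPKM in the knockdown, at least 79.5-fold higher. Mitochondrially encoded mt:ATPase6 was 450 times its wildtype level, with a 95% counting interval from 80.2 to 17800 because wildtype held a single read. For CG31269 the ratio was 395 (interval 70.4 to 15700), and for 1 gene without a current symbol it was 72.2 (24.3 to 354). Mitochondrially encoded mt:CoI rose from 0.652 ± 0.226 to 12.4 ± 0.893 RPKM. Among the other mitochondrial genes, mt:srRNA and mt:ND4L had 0 reads and mt:ND3 1 read over all 6 libraries, while mt:Cyt-b had 57, 55 and 0 and mt:ND5 61, 73 and 0 reads in the Zeus knockdown, the Caf40 knockdown and wildtype. As mt:ATPase6 and mt:CoI rose in both knockdowns and genes that every cell uses were at 0, these folds were not read as changes of expression due to the knockdown. The metallothionein MtnD rose from 0.378 to 6.21 RPKM (adjusted p = 0.000377). Of these largest rises, Henna, CG13675, CG17177, CG17477, CG31269, MtnD, mt:ATPase6 and mt:CoI were also at least 16-fold in the Caf40 knockdown. They were thus not particular to the Zeus knockdown. Intervals and lower bounds cover counting error only.

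Among the 12 largest falls, the gustatory receptor gene Gr93d had no reads in the Zeus knockdown and 9.80 ± 1.23 RPKM in wildtype, at least 133-fold lower. RabX2 was at least 137-fold lower and lncRNA:CR40469 at least 27.6-fold lower. With 1 to 3 reads left in the knockdown, wildtype exceeded it 243-fold for CG31205 (interval 43.3 to 9620), 184-fold for CG12268 (62.8 to 896), 147-fold for CG8960 (40.6 to 1220) and 121-fold for lncRNA:CR41352 (33.2 to 1000). CG16727 fell from 10.8 to 0.0913 RPKM, the prolyl 4-hydroxylase gene PH4alphaNE3 from 5.33 to 0.0647 RPKM and the neuropeptide gene AstCC from 7.58 to 0.0812 RPKM, with log2 fold changes of -6.86, -6.05 and -5.99. All of the 12 falls except Gr93d were also at least 16-fold in the Caf40 knockdown, so they were not particular to the Zeus knockdown. Mur18B also came under the rule, at 0.173 and 18.7 RPKM in the wildtype libraries, and its call rested on wildtype replicate 2. Without that library its log2 fold change was -2.91 (adjusted p = 0.167).

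The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count of 3761 changed genes moved with single libraries, to 2127 and 1625 without Zeus knockdown replicate 1 or 2, 2107 and 1824 without wildtype replicate 1 or 2, and 5348 and 5360 without Caf40 knockdown replicate 1 or 2. Rises made up 45.6% of the changed genes, 21.9% with scaling by library total and 65.0% with libraries scaled to the same median, so the balance of rises and falls varied with the scaling.

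Some genes of late spermatogenesis rose and some ribosomal protein genes fell in the Zeus knockdown, while most members of the postmeiotic, axoneme and ribosomal lists did not pass the test. Of 26 postmeiotic spermatid genes, 11 rose and 0 fell, and the same list adjusted over the list alone gave 13 and 0 (median log2 fold change 0.30, camera adjusted p = 0.000495, and adjusted p = 0.808 with an estimated correlation). Mst84Db, a sperm-tail protein gene, rose from 2245 ± 80.9 to 3173 ± 71.1 RPKM (SD, n = 2). The largest changes in that list belonged to genes without a known spermatid function, dj-1beta, an oxidative-stress response gene (17.5 to 33.2 RPKM), and Mst57Da, an accessory gland peptide gene that a second list also holds (0.223 to 2.11 RPKM). Of 18 comet and cup genes, which are transcribed after meiosis, 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 0.0314, and adjusted p = 0.808 with an estimated correlation), among them d-cup from 50.9 to 72.9 RPKM and boly from 336 to 444 RPKM, while cutlet, related to a clamp-loader subunit of DNA replication, fell from 3.97 to 1.252 RPKM. These counts moved with single libraries. Without Zeus knockdown replicate 1 or 2, 4 and 3 postmeiotic and 3 and 5 comet and cup genes rose, without wildtype replicate 1 or 2, 3 and 4 postmeiotic and 5 and 2 comet and cup genes, and without either Caf40 knockdown replicate 24 and 14. With limma on log2(RPKM + 1), 5 postmeiotic genes rose and 1 fell (median 0.15), and with quantile normalization before the same test 4 rose and 1 fell (median -0.03), so the sign of that median depended on the normalization. The comet and cup median was 0.18 with limma and 0.16 after quantile normalization, and with scaling by library total the medians of these lists were 0.14 and 0.17.

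Of 17 dynein and axoneme genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.23, camera adjusted p = 0.00349, and adjusted p = 0.808 with an estimated correlation). Without Zeus knockdown replicate 1 or 2 or wildtype replicate 2, 3 of them rose, and 14 without either Caf40 knockdown replicate. The axoneme median was 0.067 with scaling by library total, 0.079 with limma and 0.072 with limma after quantile normalization. Dhc62B, an axonemal dynein heavy chain, rose from 16.6 to 20.4 RPKM, a call that was lost without Zeus knockdown replicate 1 or 2 or wildtype replicate 2 (log2 fold change 0.44, 0.44 and 0.39). The other large changes of that list were in Sdic2, Sdic3 and Sdic4, which rose by log2 1.29, 1.85 and 1.13 but are near-identical tandem copies, so the split of reads among them is uncertain. Of 81 cytoplasmic ribosomal protein genes, 0 rose and 34 fell (0 and 38 adjusted over the list alone, median -0.24, camera adjusted p = 0.00109, and adjusted p = 0.872 with an estimated correlation). The falls numbered 5 and 4 without Zeus knockdown replicate 1 or 2, 28 and 2 without wildtype replicate 1 or 2, and 58 and 59 without Caf40 knockdown replicate 1 or 2. They numbered 66 (median -0.40) with scaling by library total and 17, with 1 rise (median -0.14), with libraries scaled to the same median. RpS15Aa fell from 41.3 to 25.6 RPKM and RpL27 from 124.8 to 78.2 RPKM. These single-gene calls were lost without 1 library, for RpS15Aa without Zeus knockdown replicate 2 (log2 fold change -0.46, adjusted p = 0.0534) and for RpL27 without wildtype replicate 2 (-0.41, adjusted p = 0.0648). Without wildtype replicate 2 the ribosomal list (median -0.14, adjusted p = 0.0976) and the comet and cup list (0.0931) lost their calls, and without Zeus knockdown replicate 1 the comet and cup list did (0.0792). The number of lists called was 7 without Zeus knockdown replicate 2 or without wildtype replicate 1, and 2 without wildtype replicate 2.

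Several genes of early germ cells and of spermatocytes fell without their lists passing the test. Of 14 meiotic arrest regulators, 0 rose and 5 fell (median -0.24, adjusted p = 0.0591), with cannonball (can), a testis-specific TAF, falling from 22.4 ± 0.913 to 10.3 ± 0.508 RPKM (SD, n = 2) and topi from 43.4 to 28.6 RPKM. Of 13 stem cell and spermatogonial genes, 0 rose and 6 fell (median -0.23, adjusted p = 0.0643), with bgcn, a partner of bam in ending spermatogonial divisions, falling from 46.1 to 27.3 RPKM and the gap junction gene zpg from 4.22 to 1.94 RPKM. Of 15 piRNA pathway genes, 1 rose and 8 fell (median -0.31, adjusted p = 0.0591), with piwi falling from 6.55 to 2.97 RPKM and aub from 11.8 to 7.26 RPKM. Of 18 replication and cell cycle genes, 1 rose and 8 fell (median -0.26, adjusted p = 0.0964), with the licensing factor dup falling from 8.10 to 4.15 RPKM and the ribonucleotide reductase subunit RnrS from 10.2 to 5.47 RPKM. Of 16 genes of spermatocyte meiosis, 1 rose and 4 fell (median -0.10, adjusted p = 0.783). The cohesin gene SA2 rose by log2 0.87, and the meiotic cohesion gene ord fell by 0.56 on the log2 scale. In these lists, in the order given, limma on log2(RPKM + 1) gave 10, 8, 10, 10 and 5 falls. The rises with it were 0, 0, 0, 0 and 1. With libraries scaled to the same median, the falls were 4, 4, 5, 4 and 2 and the rises 1, 1, 1, 3 and 1. Without Zeus knockdown replicate 1 or 2 or wildtype replicate 1 or 2, the falls numbered 4, 3, 4 and 3 in the meiotic arrest, 5, 4, 6 and 3 in the piRNA, 5, 2, 4 and 3 in the replication and 2, 2, 2 and 3 in the spermatocyte meiosis list. Without either Caf40 knockdown replicate 8 meiotic arrest genes fell. By camera with preset correlation, the meiotic arrest list passed without Zeus knockdown replicate 2 (adjusted p = 0.039) or Caf40 knockdown replicate 1 (0.0477), the stem cell list without Caf40 knockdown replicate 1 or 2 (0.0477 and 0.0453), and the piRNA list without wildtype replicate 1 (0.0399). With an estimated correlation none of these passed (adjusted p from 0.509 to 0.863).

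Lists of testis somatic cells and sheath, of tissues that a dissection can carry over, and of immune and heat shock genes were also measured. Of 16 muscle sheath genes, 8 rose and 1 fell (median 0.42, adjusted p = 0.0554), with the actin gene Act57B rising from 6.67 to 11.2 RPKM. Of 8 accessory gland and duct genes, 4 rose and 1 fell (median 0.53, adjusted p = 0.0616), with Mst57Db rising from 0.636 to 3.67 RPKM. The cyst and hub cell list had 2 rises and 2 falls of 17 (median -0.07, adjusted p = 0.876), among them sine oculis (so) rising from 4.59 to 7.93 RPKM. The fat body list had 1 rise and 2 falls of 7 (median -0.26, adjusted p = 0.334), with Apoltp falling from 4.08 to 1.80 RPKM, and the gut list 2 rises and 1 fall of 7 (median 0.14, adjusted p = 0.286), with the amylase gene Amy-d rising from 1.68 to 5.19 RPKM. Of 9 antimicrobial peptide and immune genes, 3 rose and 1 fell (median 0.35, adjusted p = 0.151), with Drosocin (Dro) rising from 0.190 to 2.49 RPKM and AttC falling from 10.8 to 4.64 RPKM. Of 10 heat shock genes, 0 rose and 3 fell (median -0.13, adjusted p = 0.292), with Hsp26 falling from 294.4 to 175.7 RPKM. Without Zeus knockdown replicate 1 or 2 or wildtype replicate 1 or 2, the rises numbered 6, 2, 5 and 3 in the muscle list and 2 each time in the accessory gland list, and no count of the other lists exceeded 4 with any 1 library left out. The muscle list passed without Zeus knockdown replicate 1 or wildtype replicate 1 (adjusted p = 0.00398 and 0.0301), the accessory gland list without Zeus knockdown replicate 2 or wildtype replicate 1 (0.0301 each) and the immune list without Zeus knockdown replicate 2 (0.039). With an estimated correlation none of these passed (adjusted p from 0.841 to 0.887). The fat body median was -0.56, -0.11, -0.43 and -0.11 without Zeus knockdown replicate 1 or 2 or wildtype replicate 1 or 2, the immune median 0.69 without wildtype replicate 2, the muscle median 0.22 without Zeus knockdown replicate 2, and the cyst and hub median 0.03 without wildtype replicate 2.

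Of 8 genes of the CCR4-NOT complex, 1 rose and 1 fell in the Zeus knockdown (median 0.11, adjusted p = 0.724). Not3 fell from 23.0 to 14.6 RPKM and Not11 rose from 11.2 to 15.4 RPKM. With libraries scaled to the same median, 3 CCR4-NOT genes rose and 1 fell (median 0.21). Of 9 genes of messenger RNA decay and P bodies, 1 rose and 2 fell (median -0.10, adjusted p = 0.751). Edc3, an activator of decapping, measured 4.65 RPKM against 6.51 in wildtype. Its call was lost without any 1 of the 4 libraries compared (log2 fold change from -0.36 to -0.30). The same held for the rise of pcm (0.23 to 0.27). The fall of PAN2 was lost without Zeus knockdown replicate 1 or 2 or wildtype replicate 2 (-0.29, -0.31 and -0.18). The testis-specific proteasome copies had 3 rises and 1 fall of 12 (median 0.12, adjusted p = 0.314), with Prosbeta5R2 rising from 66.9 to 92.7 RPKM, and the general proteasome subunits 3 rises and 3 falls of 26 (median -0.01, adjusted p = 0.936), with Prosbeta2 falling from 51.7 to 34.2 RPKM, a call lost without wildtype replicate 2 (log2 fold change -0.36, adjusted p = 0.0654). Testis-specific mitochondrial copies had 4 rises and 1 fall of 22 (median 0.12, adjusted p = 0.292), with Scsalpha2 at 456 against 387 RPKM, a call lost without any 1 of the 4 libraries compared (adjusted p from 0.103 to 0.129), and Y-linked fertility genes 1 rise and 0 falls of 5 (median 0.19, adjusted p = 0.323). Without any 1 of the 4 libraries compared, 1 testis-specific proteasome copy and 0 testis-specific mitochondrial copies rose, and without either Caf40 knockdown replicate 6 and 11 did. General proteasome falls numbered 1, 1, 3 and 0 without Zeus knockdown replicate 1 or 2 or wildtype replicate 1 or 2, and 8 without either Caf40 knockdown replicate. Medians this close to 0 took the other sign under at least 1 other scaling for the CCR4-NOT, decay, spermatocyte meiosis, cyst and hub, gut, general proteasome, testis proteasome and testis mitochondrial lists.

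Most of the testis transcriptome changed in the Caf40 knockdown. Of 10223 genes, 4281 rose and 3949 fell, which was 80.5% of the genes, with a median size of the log2 fold change of 0.78, and 2110 rose and 1781 fell at least 2-fold. Most listed genes of DNA replication, ribosomes and the piRNA pathway rose, and most listed genes of meiotic arrest, spermatid differentiation and testis-specific mitochondria and proteasomes fell. None of the 10 list calls held with an estimated correlation (adjusted p from 0.688 to 0.703). All 10 passed fry, which asks a different question (fry adjusted p from 0.00118 to 0.0198). The gap junction gene zpg rose from 4.22 ± 0.112 to 54.5 ± 9.01 RPKM (SD, n = 2) and bam, which ends spermatogonial divisions, from 3.32 ± 0.128 to 36.6 ± 6.29 RPKM, while fzo, the mitofusin of spermatids, fell from 119.1 ± 14.1 to 36.7 ± 3.6 RPKM.

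The largest rises included CG16772, from 8.51 ± 3.45 to 306.4 ± 7.16 RPKM (SD, n = 2, log2 fold change 4.95, SE 0.22, adjusted p = 1.44e-10). CG3348 rose from 0.233 to 14.6 RPKM, CG15422 from 0.779 to 29.2 RPKM and CG13116 from 0.860 to 25 RPKM, with log2 fold changes of 5.64, 4.96 and 4.63. The mitochondrially encoded mt:CoI rose from 0.652 to 18.8 RPKM, and mt:ATPase6 and mt:CoII exceeded wildtype by ratios of 567 (interval 101 to 22500) and 86.4 (23.4 to 722), with the same limits on the mitochondrial values as in the Zeus knockdown. CG31269 exceeded it by a ratio of 333 (59.2 to 13200) and the immune peptide gene BomS2 by 87.9 (23.8 to 735), the latter at 8.73 ± 7.80 RPKM and so uneven between the knockdown libraries. MtnD, CG17177 and CG13675, which were also among the largest rises of the Zeus knockdown, rose by log2 4.62, 4.54 and 4.48.

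The largest falls included TyrR, a tyramine receptor, from 13.3 ± 2.08 to 0.119 ± 0.0724 RPKM (SD, n = 2, log2 fold change -6.89, SE 0.27, adjusted p = 6.47e-11), CG14369 from 32.3 to 0.416 RPKM (-6.57) and CG16727 from 10.8 to 0.0956 RPKM (-7.06). CG33342 had no reads in the knockdown and was at least 48.8-fold lower. Wildtype exceeded the knockdown 356-fold for the prolyl 4-hydroxylase gene PH4alphaNE1 (interval 121 to 1730), 216-fold for CG31205 (38.6 to 8570) and for lncRNA:CR41352 (38.5 to 8550), 183-fold for RabX2 (50.4 to 1520), 173-fold for AANATL4 (30.7 to 6840), 131-fold for AstCC (36.1 to 1090) and 91.3-fold for PH4alphaNE3 (31.0 to 445). Mur18B had 1 read in the knockdown, and its call again rested on wildtype replicate 2 (log2 fold change -3.09 without it, adjusted p = 0.0582). Rises made up 52.0% of the changed genes, 61.1% with scaling by library total and 39.8% with libraries scaled to the same median.

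Nearly all listed cytoplasmic ribosomal protein and replication genes rose in the Caf40 knockdown. Of 81 cytoplasmic ribosomal protein genes, 78 rose and 2 fell, with the same counts adjusted over the list alone (median log2 fold change 1.90, camera adjusted p = 2.31e-33, and adjusted p = 0.688 with an estimated correlation). RpS5b rose from 79.9 ± 7.96 to 505 ± 69.7 RPKM (SD, n = 2), RpL18 from 106.5 to 595.9 RPKM, RpL13 from 142.2 to 686.4 RPKM and RpS4 from 156.9 to 776.2 RPKM. Of 18 replication and cell cycle genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone, median 1.72, camera adjusted p = 4.42e-08, and adjusted p = 0.688 with an estimated correlation). The ribonucleotide reductase subunit RnrL rose from 2.72 to 27.6 RPKM, the helicase subunits Mcm7 from 5.62 to 32.0 RPKM and Mcm5 from 3.88 to 23.6 RPKM, and PCNA from 29.0 to 142.8 RPKM.

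Many genes expressed early in the germline also rose. Of 15 piRNA pathway genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.83, camera adjusted p = 0.00115), with shu rising from 3.37 to 39.0 RPKM, tej from 1.69 to 21.5 RPKM, aub from 11.8 to 79.0 RPKM and egg, an H3K9 methyltransferase, by log2 1.80. Of 13 stem cell and spermatogonial genes, 7 rose and 3 fell (median 0.69, adjusted p = 0.0521, not past the threshold but past it without Zeus knockdown replicate 1 or 2 or Caf40 knockdown replicate 2, at 0.0398, 0.0403 and 0.0306, and at adjusted p from 0.384 to 0.761 with an estimated correlation), with pum rising by log2 1.55 and Nurf-38 by 1.18 besides zpg and bam. Of 26 general proteasome subunits, 17 rose and 1 fell (17 and 0 adjusted over the list alone, median 0.35, camera adjusted p = 0.0108), with Rpn12 rising from 17.3 to 108.9 RPKM and Rpt3 from 13.4 to 60.4 RPKM. With libraries scaled to the same median, 9 of these subunits rose and 6 fell (median 0.05), and with limma 21 rose, or all 26 after quantile normalization, so their balance depended on the normalization. With an estimated correlation the piRNA and general proteasome calls were lost, each with adjusted p = 0.688.

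Most listed genes of meiotic entry and spermatid differentiation fell. Of 14 meiotic arrest regulators, 13 fell and 1 rose (the same adjusted over the list alone, median -0.77, camera adjusted p = 0.00177), with can falling from 22.4 to 7.25 RPKM, topi from 43.4 to 19.0 RPKM and the testis-specific TAF spermatocyte arrest (sa) from 51.5 to 21.8 RPKM. Of 26 postmeiotic spermatid genes, 19 fell and 1 rose (the same adjusted over the list alone, median -0.61, camera adjusted p = 0.00437), with fzo falling by 1.92 and the sperm chromatin gene Prtl99C by 1.38 on the log2 scale, and dj-1beta, which is not specific to spermatids, rising from 17.5 to 76.0 RPKM. Of 18 comet and cup genes, 14 fell and 0 rose (the same adjusted over the list alone, median -0.77, camera adjusted p = 0.00321), with soti, a regulator of caspase activity in spermatids, falling from 363.5 to 112.1 RPKM, sunz from 95.2 to 29.5 RPKM and r-cup from 60.5 to 33.2 RPKM. With an estimated correlation these calls were lost (adjusted p = 0.688 for the meiotic arrest and comet and cup lists and adjusted p = 0.703 for the postmeiotic list). The postmeiotic median was -0.39 with scaling by library total.

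Nearly all testis-specific copies of housekeeping complexes fell, while most ribosomal protein genes rose. All 22 testis-specific mitochondrial copies fell (the same adjusted over the list alone, median -1.08, camera adjusted p = 5.87e-06), with Tim17a1 falling from 121.7 to 40.6 RPKM and ATPsynGL from 196.0 to 64.8 RPKM. Of 12 testis-specific proteasome copies, 11 fell and 0 rose (the same adjusted over the list alone, median -1.15, camera adjusted p = 0.00115), with Prosbeta2R2 falling from 69.1 to 26 RPKM and Rpt6R from 120.5 to 62.0 RPKM. Of 17 dynein and axoneme genes, 12 fell and 1 rose (the same adjusted over the list alone, median -0.87, camera adjusted p = 0.0053), with Dhc36C falling from 44.0 to 17.5 RPKM and Tektin-A from 197.2 to 100.5 RPKM. The 5 Y-linked fertility genes all fell, as kl-2, a Y-linked axonemal dynein, from 7.58 to 2.82 RPKM and ORY from 8.10 to 3.03 RPKM, and the list did not pass the threshold (median -0.75, adjusted p = 0.0521). It passed without Zeus knockdown replicate 1 or 2 (0.0374 and 0.039), wildtype replicate 1 (0.049) or Caf40 knockdown replicate 2 (median -1.35, adjusted p = 0.0479), though not with an estimated correlation (adjusted p from 0.384 to 0.785). With an estimated correlation the calls of the mitochondrial, proteasome and axoneme lists were lost (adjusted p = 0.688).

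Other lists moved both ways in the Caf40 knockdown. Of 16 genes of spermatocyte meiosis, 8 rose and 8 fell (adjusted p = 0.83), with the meiotic translation regulator bol falling from 379.8 to 159.8 RPKM, the Cdc25 phosphatase gene twe from 63.2 to 32.9 RPKM, and tef and sunn rising by log2 2.06 and 2.42. The median of that list was -0.10 and its mean 0.09, which differ in sign. Of 8 CCR4-NOT genes, 3 rose and 4 fell (median -0.15, adjusted p = 0.727), with Rga rising from 11.2 to 31.3 RPKM and Not3 from 23.0 to 50.8 RPKM, twin, a deadenylase subunit, falling by 1.07, and Rcd-1 the strongest fall. Of 9 decay and P body genes, 3 rose and 3 fell (median -0.02, adjusted p = 0.83), with the exosome nuclease Rrp6 falling from 134.3 to 72.3 RPKM and Edc3 rising from 6.51 to 12.6 RPKM.

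Of 17 cyst and hub genes, 8 rose and 5 fell (median 0.16, adjusted p = 0.963), with CadN falling by 1.64, the hub ligand gene upd1 by 1.29 and cora rising by 1.10 on the log2 scale. The muscle sheath list had 7 rises and 2 falls of 16 (median 0.28, adjusted p = 0.897), with sls falling from 7.26 to 3.59 RPKM and Tm1 rising from 9.88 to 23.9 RPKM. The fat body list had 5 rises and 2 falls of 7 (median 0.85, adjusted p = 0.328), with transferrin (Tsf1) rising from 160.9 to 561.5 RPKM and the lipid-droplet gene Lsd-1 by log2 2.26. The gut list had 3 rises and 2 falls of 7 (median -0.13, adjusted p = 0.963), with Amy-p rising from 3.62 to 15.5 RPKM and salt falling from 3.03 to 0.224 RPKM. The accessory gland list had 2 rises and 4 falls of 8 (median -0.93, adjusted p = 0.528), with Acp36DE falling by 1.81 and Gld rising by 1.76. Of 9 antimicrobial peptide and immune genes, 6 rose and 1 fell (median 1.95, adjusted p = 0.424), with PGRP-SA, AttB and Dro rising by log2 2.21, 2.71 and 3.66. Of 10 heat shock genes, 4 rose and 2 fell (median 0.03, adjusted p = 0.989), with Hsp27 rising from 203.9 to 490.1 RPKM and Hsp68 falling from 99.3 to 62.1 RPKM. The medians of the CCR4-NOT, decay, spermatocyte meiosis, cyst and hub, muscle, gut and heat shock lists took the other sign under at least 1 other scaling. The accessory gland median was -0.28 without wildtype replicate 1. Without Caf40 knockdown replicate 1 or 2 the muscle median was -0.02 and 0.47 and the cyst and hub median 0.04 and 0.30, the latter being 0.27 without wildtype replicate 2.

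**Figure D2:**
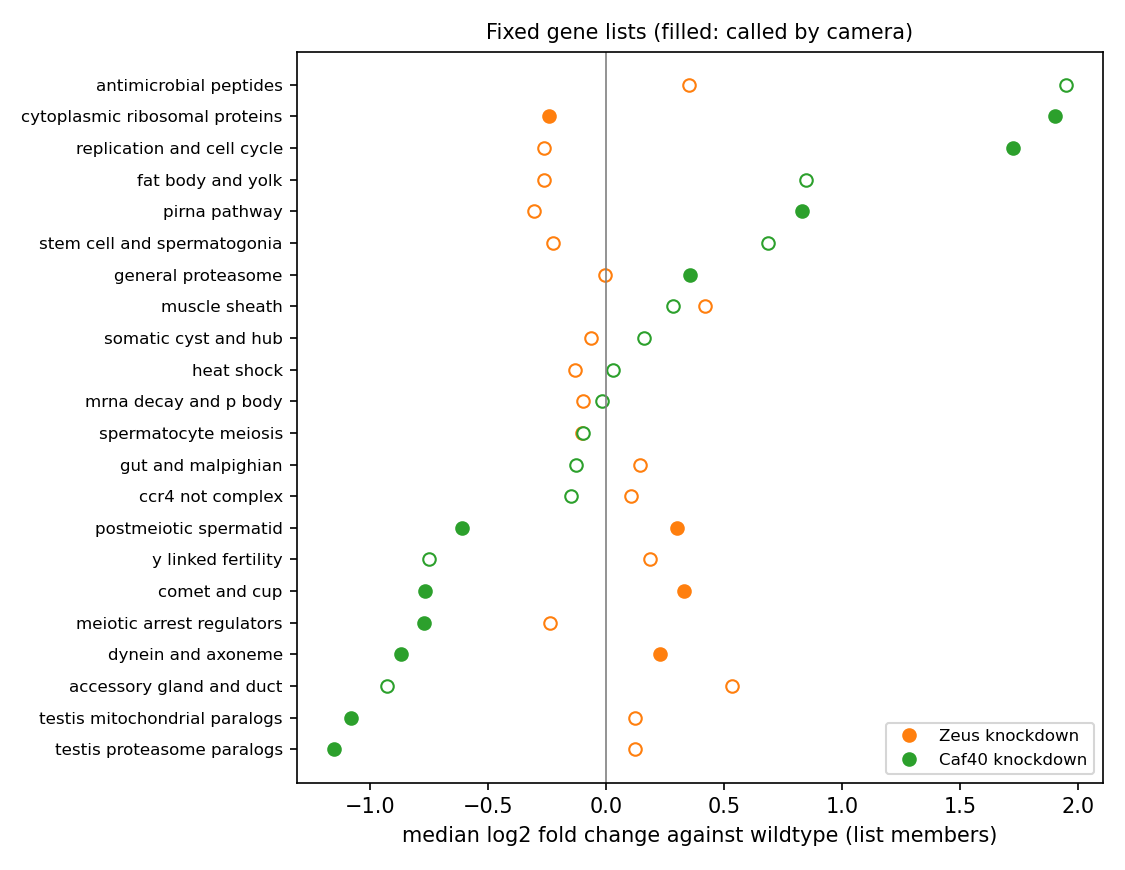
Median log2 fold change against wildtype of each of the 22 fixed gene lists in the Zeus knockdown and the Caf40 knockdown. Filled points passed the camera test with a preset correlation (4 lists in the Zeus knockdown, 10 in the Caf40 knockdown), open points did not, and the ribosomal list lies at -0.24 and 1.90. None of these calls held with an estimated correlation (0 lists in each knockdown). The Zeus median of the postmeiotic list, 0.30 here, was 0.15 with limma and -0.03 with limma after quantile normalization.

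The knockdowns differed directly from each other in most genes. In the Zeus minus Caf40 comparison 4108 genes were higher in the Zeus knockdown and 4427 lower, 83.5% of those tested. Arr1, an arrestin of photoreceptors, was 30.3 ± 0.113 RPKM in the Zeus knockdown against 2.93 ± 0.580 RPKM in the Caf40 knockdown (SD, n = 2, log2 difference 3.72, SE 0.14, adjusted p = 2.84e-11), and the checkpoint adaptor gene Claspin 0.157 ± 0.00207 against 7.91 ± 1.33 RPKM (log2 difference -5.26, SE 0.21, adjusted p = 5.17e-11). Higher in the Zeus knockdown were also CG14369 (13.7 against 0.416 RPKM), CG6154 (10.3 against 0.716), DIP-delta (22.2 against 2.04), CG13203, CG32053 and CG30377, with log2 differences of 5.49, 4.18, 3.79, 3.69, 3.35 and 3.25, and CG13230, which was at least 17.8-fold higher. Lower were CG3348 (log2 difference -5.07), CG16772 (-4.84), CG4757 (-4.69) and 1 gene without a current symbol (-5.05). The Caf40 knockdown exceeded the Zeus knockdown by a ratio of 283 for Oxp (interval 50.3 to 11200) and 111 for CG15422 (37.5 to 540), and snoRNA:Me28S-U2134a, at least 4.49-fold lower in the Zeus knockdown, lost its call without Zeus knockdown replicate 2 (adjusted p = 0.0631).

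Of the 22 lists, 7 were higher in the Zeus than in the Caf40 knockdown by camera with preset correlation, and with an estimated correlation none of the 12 calls between the knockdowns held (adjusted p from 0.526 to 0.561). The 7 lists were the testis-specific proteasome (median log2 difference 1.29, adjusted p = 0.000374), testis-specific mitochondrial (1.28, 3.46e-06), dynein and axoneme (1.27, 0.000143), Y-linked (1.03, 0.03), comet and cup (0.98, 0.000162), postmeiotic (0.94, 3.31e-05) and meiotic arrest lists (0.57, 0.044). The ribosomal (-2.14, 4.58e-36), replication (-1.90, 2.5e-08), piRNA (-1.34, 0.000143), stem cell and spermatogonial (-1.22, 0.0144) and general proteasome lists (-0.32, 0.0185) were lower. The meiotic arrest call was lost without Zeus knockdown replicate 2 or Caf40 knockdown replicate 1 or 2 (adjusted p = 0.0706, 0.15 and 0.284), the Y-linked call without Caf40 knockdown replicate 1 (0.085), and the general proteasome call with libraries scaled to the same median (0.0632), where its median was 0.08. With scaling by library total the median difference was 0.19 for the meiotic arrest, 0.56 for the postmeiotic, 0.60 for the comet and cup, 0.65 for the Y-linked and -0.71 for the general proteasome list. Rises made up 48.1% of the genes that differed, 36.5% with scaling by library total and 61.2% with libraries scaled to the same median.

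The direction of change was shared for most of the largest changes in the Zeus knockdown and not for most of the small ones. Of 2984 genes called in both knockdowns, 1105 moved the same way (482 up and 623 down) and 1879 opposite ways (794 up in Zeus and down in Caf40, 1085 the reverse). Independent lists of these sizes would share 1508.5 genes in the same direction and 1519.3 in opposite directions. The 100 simulated draws held unchanged groups and redrawn wildtype libraries shared by both comparisons. In them a mean of 0.34 genes and at most 3 were called in both in the same direction, and 0 in opposite directions. Of the 3161 genes called in the Zeus knockdown with a log2 fold change under 1 in size, 23.8% were called in the same and 56.3% in the opposite direction in the Caf40 knockdown. The corresponding shares were 50.0% and 20.4% for sizes from 1 to 2, 75.9% and 9.48% from 2 to 4, and 91.4% and 1.72% from 4 upward. Both fold changes use the same wildtype libraries, which favours the same direction where the Zeus change is large. Without a driver-only library, background and knockdown could not be told apart for the largest changes.

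**Figure D3:**
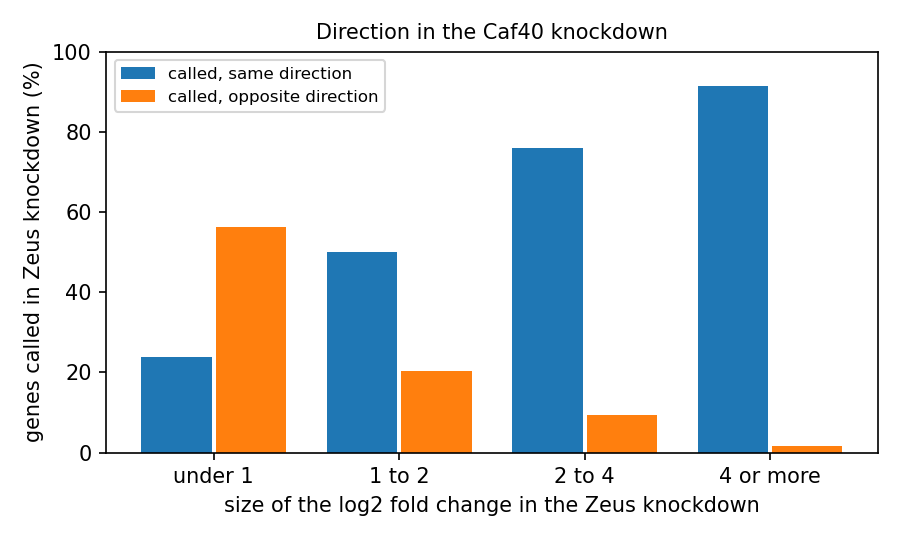
Share of the genes called in the Zeus knockdown (%) that were called in the same or the opposite direction in the Caf40 knockdown, by the size of the log2 fold change in the Zeus knockdown. Bars for changes under 1 stand at 23.8% and 56.3%, and those for changes of 4 or more at 91.4% and 1.72%.

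At least 16-fold changes in the same direction in both knockdowns were found for 32 genes, 12 higher and 20 lower, and none changed that much in opposite directions. Besides genes named above, such as RabX2 and CG17477, they held the neural transcription factor gene dpn, with no reads in wildtype, and the P450 gene Cyp6g1, at 16.3 and 28.4 RPKM in wildtype and between 0.215 and 1.42 RPKM in the 4 knockdown libraries. These last genes were chosen after their values were seen. The 12 higher genes include mt:ATPase6, mt:CoI, mt:CoII and mt:ND2, to which the limits on mitochondrial values given above apply. The 20 lower genes include Mur18B, whose call rested on wildtype replicate 2. Across genes, which are not independent replicates, the log2 fold changes of the knockdowns had a Pearson correlation of 0.209 and a Spearman correlation of -0.15. The mean Pearson correlation in the simulated draws was 0.429. The draws held no changed genes, so that value reflects only the shared wildtype libraries and does not show less agreement in the data. The covariance of the log2 fold changes was 0.182 against 0.0207 in the draws, a difference of 0.162. The 2 wildtype libraries could not be split into groups of 2, so part of any excess may come from the shared controls.

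The excess of opposite directions was not stable. After quantile normalization 709 genes moved in opposite and 935 in the same directions, and among changes of at least 2-fold the numbers were 53 and 273. Without wildtype replicate 2 they were 608 and 706, without wildtype replicate 1 855 and 636, and without Zeus knockdown replicate 1 or 2 865 and 758 or 646 and 610. Without Caf40 knockdown replicate 1 or 2 they were 2892 and 1456 or 3176 and 1351.

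Genes on the X chromosome were over-represented among those that rose in the Caf40 knockdown, where they made up 680 of 3718 located genes (18.3% against 16.2% of tested genes, odds ratio 1.30, 95% interval 1.16 to 1.46, Fisher's exact test, adjusted p = 6.3e-05 over 36 tests). They were under-represented among those that fell (14.0%, odds ratio 0.766, adjusted p = 6.3e-05). Of the 54 tested genes on chromosome 4, 38 rose in the Caf40 knockdown (odds ratio 3.37, adjusted p = 0.000109) and 6 fell (odds ratio 0.194, adjusted p = 6.3e-05). Among changes of at least 2-fold, 7 rose (odds ratio 0.588, 95% interval 0.224 to 1.31, adjusted p = 0.443) and 3 fell (odds ratio 0.2725, adjusted p = 0.0732), neither past the threshold. Arm 2L held more of the genes that fell (odds ratio 1.28, adjusted p = 6.3e-05) and fewer of those that rose (0.812, adjusted p = 0.00072). In the Zeus knockdown the X chromosome held 16.8% of the genes that rose (odds ratio 1.05, adjusted p = 0.655). Among rises of at least 2-fold its odds ratio was 0.638 (Fisher's exact test, adjusted p = 0.0893). It held 14.46% of the genes that fell (0.849, adjusted p = 0.0648), which passed with libraries scaled to the same median (0.789, adjusted p = 0.0227). Arm 3L held fewer of the genes that rose in the Zeus knockdown (0.787, adjusted p = 0.00385), as did chromosome 4 (2 genes, 0.188, adjusted p = 0.0143). The calls for 3L, for chromosome 4 and for 2L among rises were lost with a 2-fold minimum, and those for 3L and for chromosome 4 among rises in the Caf40 knockdown also with libraries scaled to the same median.

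The D. simulans and D. yakuba libraries could be described only as single libraries, because their gene identifiers shared 0 entries with those of D. melanogaster or with each other. Reads assigned to genes made up 74.9% of mapped reads in D. simulans and 78.7% in D. yakuba, against 97.1% to 98.0% in the D. melanogaster libraries. An RPKM of at least 1 was reached by 10064 of 16034 listed genes in D. simulans and 10206 of 16811 in D. yakuba. The most abundant gene took 1.59% and 1.39% of the gene reads, and the 100 most abundant genes 24.7% and 24.0%. Junction reads made up 1.59% and 1.81% of mapped reads, against 2.09% to 2.32% in D. melanogaster. Listed lengths were multiples of 3 for 97.4% and 97.0% of genes in D. simulans and D. yakuba and for 45.2% in D. melanogaster, so they are coding lengths without untranslated regions in the former species and RPKM cannot be compared across species as it stands.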

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

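All of the tests of explanations in this part were chosen after the results were seen, while the Zeus minus Caf40 contrast was planned. These results drew attention because the knockdowns moved apart in a test of the difference itself. The median log2 difference, Zeus minus Caf40 knockdown, was 0.938 for postmeiotic spermatid genes, 0.975 for comet and cup genes, 1.27 for dynein and axoneme genes and -2.14 for cytoplasmic ribosomal protein genes. For the gene Rcd-1r the difference was -4.56 (adjusted p = 8.14e-12), lower in both Zeus knockdown libraries than in both Caf40 knockdown libraries. The list calls were lost with an estimated correlation (adjusted p from 0.526 to 0.553).

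The first pattern is the set of 32 genes changed at least 16-fold in the same direction in both knockdowns. It includes mt:ATPase6, mt:CoI, mt:CoII and mt:ND2, with the limits given above, and Mur18B, whose call rested on wildtype replicate 2. Spread of the shared wildtype libraries at the fitted dispersion gave no gene with such a change in both knockdowns, as the highest number in 100 simulated draws was 0. The draws held no real difference and redrew the wildtype libraries. They could therefore not exclude wildtype libraries that themselves differ from both knockdowns. Loss of the same target gene remained undecided, because Rcd-1 had a log2 fold change of -0.15 in the Zeus knockdown that passed the threshold only under some alternatives, such as scaling by library total (adjusted p = 0.00908), while Rcd-1r moved in opposite directions. A genetic background shared by the knockdown flies and not by the wildtype flies may also contribute, as 2 pairs of direct neighbours among the 28 located genes exceeded the mean of 0.0854 over 10000 random orders (highest 3, permutation p = 0.0028), but an equal number of genes changed only in the Caf40 knockdown also held 2 such pairs. Without a driver-only library, background and knockdown cannot be told apart for these genes.

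The second pattern is the excess of opposite over same directions among genes called in both knockdowns. Scaling by 1 factor per library could not be excluded. The ratio of opposite to same directions stayed at 1.65 or more under 3 other such scalings. However, each of these shifted the median log2 fold changes of the knockdowns in opposite directions, so a scaling that moves both alike was not tried. The shifts for Zeus and Caf40 were -0.16 and 0.22 with library total, 0.10 and -0.30 with the same median. With DESeq2 size factors they were only 0.02 and -0.06. A difference between libraries in the shape of the expression distribution had the values it needs, since quantile normalization lowered the ratio to 0.758 where the same limma test without it gave 1.86. Shares of early and late germ cells that moved apart in the knockdowns may underlie such a difference in shape and stayed undecided, because 9 of the 11 fixed germ-cell lists had medians of opposite sign but the meiotic arrest and spermatocyte meiosis lists had the same sign, and with limma 8 of the 11 differed in sign without and 6 with quantile normalization. The ratio also fell below 1 without wildtype replicate 2 (0.861), so the excess rests in part on single libraries.

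The third pattern is the rise of Rcd-1r in the Caf40 knockdown. Reads shared between Rcd-1 and Rcd-1r were excluded as its source, since such reads would fall with Rcd-1, and Rcd-1r rose by log2 2.12 (SE 0.10). A larger share of early germ cells in these testes may raise Rcd-1r along with other early transcripts and could not be decided, as 6 of 27 early germ-cell list members (bam, zpg, aub, tej, rhi and shu) rose at least as much, over a range from -0.92 to 3.45. A response of Rcd-1r to the loss of Rcd-1, which is what the design names, stays open and was not tested apart from it.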

How the results depend on the processing

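Scaling by library total, DESeq2 size factors in edgeR, list medians with limma and list tests with 1 library left out were chosen after the data were seen, and the other alternatives were planned. Among named genes, lists and arms, 4464 values kept their side of the threshold, 265 lost their call and 32 gained one. In 1 further case a called value reversed, the odds ratio of chromosome 4 among rises in the Caf40 knockdown, 0.588 with a 2-fold minimum. Changes of direction in values called under neither setting were not counted as reversals. This tally leaves out the targets and the X chromosome in the comparisons with wildtype, where 9 further values gained a call. The Zeus count of 3761 was 2215 after quantile normalization, 600 with a 2-fold minimum, and 1625 to 5360 with 1 library left out. The Caf40 count of 8230 was 3891 and the count between knockdowns of 8535 was 4640 with the 2-fold minimum, where fewer genes can pass by construction. Leaving out 1 library gave 7443 to 8347 and 7854 to 8545. The same-direction overlap of 1105 was 273 with the 2-fold minimum and 610 to 1456 with 1 library left out. The opposite-direction overlap of 1879 was 709 after quantile normalization, 2842 with only the 4 libraries compared, 53 with the 2-fold minimum and 608 to 3176 with 1 library left out. Rcd-1 in the Zeus knockdown (-0.15) passed the threshold with limma at pseudocounts of 1, 0.1 and 5 (-0.29, -0.30 and -0.28), scaling by library total (-0.31), quantile normalization (-0.27), the 4 libraries alone (-0.14), and without Caf40 knockdown replicate 1 or 2 (-0.14 each), and ranged from -0.17 to -0.12 with 1 library left out. With an estimated correlation 0 lists were called in each contrast, against 4, 10 and 12. That correlation itself moved with single libraries. Without Caf40 knockdown replicate 2 it went from 0.73 to -0.03 for the postmeiotic and from 0.64 to -0.05 for the replication list. For the ribosomal list it was 0.74 with and 0.77 without that library. A call lost this way therefore does not show that a list was unchanged. Fry, which asks a different question, called 2 in the Zeus and 17 in the Caf40 knockdown. The 2 Zeus lists were meiotic arrest and heat shock (fry adjusted p = 0.0174 each), neither of them called by camera. The 4 Zeus lists that camera called did not pass fry (fry adjusted p from 0.0847 to 0.132), while the 10 Caf40 lists that camera called did (0.00118 to 0.0198). With 1 library left out, 2 to 7, 10 to 12 and 10 to 12 lists were called. X-linked genes among falls in the Zeus knockdown passed with libraries scaled to the same median (odds ratio 0.789). Apart from the 2-fold minimum and the smaller sets of libraries, the cause was not tested.

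Replicate numbers did not pair the libraries (correlations of deviations 0.0218, -0.0367 and -0.0517). With the replicate number as a block, 3615, 8169 and 8479 genes were called, 1060 overlapped in the same and 1779 in opposite directions, and 5, 12 and 12 lists passed. The comparisons across species and their alternatives were not run, since no identifiers were shared. Low genes are limited by depth, as 3 reads on 1 kb are 0.120 to 0.232 RPKM.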

Other observations

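All tests in this part were chosen after the values were seen, on 10 gene families picked by symbol. Beyond the lists described above, some further families of protein synthesis genes rose in the Caf40 knockdown. Of 31 aminoacyl-tRNA synthetase genes, which charge transfer RNAs, 26 rose and 5 fell (median log2 fold change 1.28, camera adjusted p = 1.59e-05, and adjusted p = 0.292 with an estimated correlation), with HisRS at 51.1 RPKM against 9.28 in wildtype and ThrRS at 96.7 against 25.4. Of 68 mitochondrial ribosomal protein genes, 49 rose and 7 fell (median 0.81, adjusted p = 0.00438, and 0.328 as the adjusted p with an estimated correlation), with mRpL1 at 34.2 RPKM against 10.1. Of 7 RNA polymerase I subunit genes, 6 rose and 0 fell (median 1.03, adjusted p = 0.0172, and adjusted p = 0.292 with an estimated correlation), with Polr1B at 13.9 RPKM against 2.21 and Polr1A at 23.9 against 4.52. All 5 Mcm genes, of which the replication list holds some, rose (median 2.27, adjusted p = 2.22e-05, and adjusted p = 0.292 with an estimated correlation). Of 21 vacuolar ATPase genes, 5 rose and 12 fell (median -0.78, adjusted p = 0.0362, and adjusted p = 0.396 with an estimated correlation), with Vha100-3 at 34.5 RPKM against 110.0 and Vha36-1 at 63.2 against 23.8, and of 43 P450 genes 8 rose and 20 fell (median -0.25, adjusted p = 0.0402, and adjusted p = 0.292 with an estimated correlation). Of 39 translation initiation genes 22 rose and 9 fell (median 0.29), which did not pass the list test (adjusted p = 0.16), and neither did the snoRNA, odorant and gustatory receptor and glutathione transferase families (adjusted p = 0.797, 0.244 and 0.78). In the Zeus knockdown none of the 10 families passed camera (lowest adjusted p 0.191, and lowest adjusted p 0.819 with an estimated correlation).

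Some genes had nearly equal values in both knockdowns and differed from wildtype. The white gene measured 88.1 and 79.1 RPKM in the Zeus knockdown, 70.8 and 79.6 in the Caf40 knockdown and 4.91 and 4.55 in wildtype. The 6 tested mitochondrially encoded protein genes had a median log2 fold change of 4.53 in the Zeus and 4.67 in the Caf40 knockdown, with a median size of the difference between knockdowns of 0.14 and 1 gene called in that difference. Without a driver-only library, genetic background and knockdown cannot be told apart for white and these mitochondrial genes. For the mitochondrial genes a further limit holds, as other mitochondrial genes that every cell uses were at 0. Their folds were therefore not read as changes of expression due to the knockdown. Of the mitochondrial genes not tested, mt:Cyt-b and mt:ND5 had 57 and 61 reads in the Zeus knockdown, 55 and 73 in the Caf40 knockdown and 0 in wildtype, while mt:srRNA and mt:ND4L had 0 in all 6 libraries. The yellow gene (y), unlike these, had no reads in the Zeus knockdown, 2.20 and 2.34 RPKM in the Caf40 knockdown and 0.117 and 0.190 RPKM in wildtype.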
